A study of Bos taurus with 32 samples.

How the data were processed

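Liver RNA of Ayrshire dairy cows was measured on Affymetrix bovine expression arrays. Energy intake in the last 6 weeks before predicted calving was either controlled (CON) or high (HIGH). Liver was biopsied at -8 d (before predicted calving) and at 1 d and 9 d after actual calving. There were 32 arrays from 12 cows, 6 per diet, which is fewer cows than the design text gives. The groups held 5 arrays (CON -8 d), 5 (HIGH -8 d), 4 (CON 1 d), 6 (HIGH 1 d), 6 (CON 9 d) and 6 (HIGH 9 d). Cow numbers in the labels, not the replicate numbers of the titles, paired the arrays, and 8 cows (3 CON and 5 HIGH) had arrays on all 3 days. Per the labels, 3 to 5 mg of liver was homogenised, RNA was extracted with RNeasy Mini columns and biotin-labelled cRNA was hybridised.

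The deposited values are log2 values that the authors made with Affymetrix Expression Console 1.1 and RMA, which corrects background, quantile normalises arrays and summarises the probes of each probe set. The RMA settings are not given in the labels. The values have 2 decimals and run from 2.35 to 15.0, with array medians of 5.87 to 5.935. RMA forces the arrays to a common distribution, so changes are relative to the bulk of probe sets, and it compresses changes of the brightest and the dimmest probe sets. The number of arrays limits the precision.

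Of 24128 probe sets, 112 controls were left out and 24016 were tested without a filter on level. Through the gene identifiers of the array annotation, 13292 carried 1 gene symbol (9155 genes), 86 carried several and 10638 carried none here. Gene values are from the probe set with the highest mean over all arrays. No genome positions were used.

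The main test was limma 3.58.1 in R 4.3.3. It fitted 6 group means with cow as a random block (consensus correlation 0.138), used empirical Bayes with a mean-variance trend (26 residual degrees of freedom before moderation), and was two-sided. P was adjusted by Benjamini-Hochberg over the 24016 probe sets for each contrast, and adjusted p under 0.05 was the threshold. The 12 contrasts were diet (HIGH minus CON) on each day, time (1 d against -8 d, 9 d against -8 d, 9 d against 1 d) averaged over the diets, time within each diet, and diet by time at 1 d and 9 d. Changes are log2 fold changes with the standard error (SE) from the fit.

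The groups, contrasts, tests, alternatives, 32 gene lists and the rule for named genes were chosen before the data were examined. The lists were fatty acid oxidation, ketogenesis, PPAR-alpha targets, gluconeogenesis, fatty acid synthesis, cholesterol synthesis, triglyceride synthesis and lipoprotein assembly, bile acid and sterol disposal, acute phase proteins, plasma proteins lowered in the acute phase, interferon-stimulated genes, endoplasmic reticulum stress, ATF4 and amino acid response, oxidative stress defence, growth hormone and IGF axis, insulin signalling and glucose handling, urea cycle and amino acid breakdown, citric acid cycle, oxidative phosphorylation, xenobiotic metabolism, cell cycle, immediate early and heat shock genes, antigen presentation, and 9 lists of markers (hepatocytes, Kupffer cells and macrophages, neutrophils, T and NK cells, B and plasma cells, erythroid cells, stellate cells and fibroblasts, endothelial cells, cholangiocytes). Named were the 10 genes with the largest rise and the 10 with the largest fall past the threshold with the same sign in both diets, or, where fewer than 5 genes passed, the 10 with the smallest p. Also named were 24 genes fixed in advance, up to 4 members with the smallest p per described list, and the 5 genes with the smallest p for diet by time. No probe set named CPT1A or FGF21 was found in the annotation used. Genes whose group means are given were chosen after their values were seen.

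Lists were tested against all other genes with the limma camera test on the moderated statistics, with a preset correlation between genes of 0.01 and, beside it, with the correlation estimated per list from the residuals. P was adjusted over the 32 lists of a contrast. As a test chosen after seeing the data, the mean of each list per array was compared between diets by exact permutation of cows and between days by exact sign flips of the cows with both days (two-sided, adjusted over the 32 lists).

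The fit was tested on simulated data with the group sizes and cows of this series and 24016 genes per comparison. Genes were drawn independently, with normal noise and the same cow correlation of 0.15 for each. On real arrays genes vary together, so the rates below need not hold there. For diet at -8 d it recovered 83% of changes of 1.5-fold and 94% of 2-fold changes, with 4.32% false calls. For diet at 1 d these were 87%, 99% and 4.62%, for diet at 9 d 91%, 99% and 3.06%, and for 1 d against -8 d 98%, 98% and 3.92%. With no effect put in and genes drawn independently, 0 of 384 list tests of the limma camera type passed after adjustment. Of 40 simulated sets with correlated genes, 20 had p under 0.05 with the preset correlation and 2 with the estimated one. These sets were all of the endoplasmic reticulum stress list, tested for diet at -8 d, with its genes strongly correlated. The strength of that correlation was not taken from the real arrays, so these shares need not hold for the lists below.

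Alternatives were no cow block, cow as a fixed effect, only the groups of the contrast, only cows with all 3 days, array quality weights, the dimmest probe sets left out, further quantile normalization, median centring, 1 probe set per gene, other variance models, a fold minimum of 1.5, and each array or cow left out in turn. Leaving out the -8 d array of cow 445 and the 9 d array of cow 528 together was added after seeing the data. Up to 100 exchanges of labels were fitted per contrast. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.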

Results

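Expression was measured in 32 liver biopsies of dairy cows fed a controlled-energy (CON) or a high-energy (HIGH) diet in the last 6 weeks before predicted calving. The groups were CON -8 d (n = 5), HIGH -8 d (n = 5), CON 1 d (n = 4), HIGH 1 d (n = 6), CON 9 d (n = 6) and HIGH 9 d (n = 6). Values are log2 RMA values. The first principal component held 16.7% of the variance and the second 10.2%. After the group means were removed, arrays of the same cow on other days correlated with a mean r of 0.323 across probe sets (28 pairs, 0.229 to 0.464), against -0.0638 for other cows of the same diet on other days (142 pairs). Probe sets are not independent replicates.

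**Figure D1:**
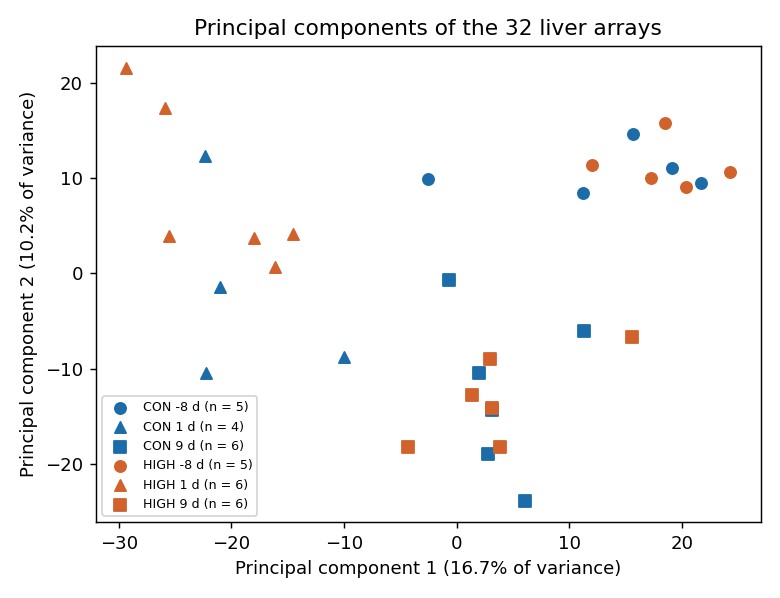
Principal components 1 and 2 (unitless scores) of the log2 values of the 32 arrays, 1 point per array, with colour for diet and shape for day. The 1 d arrays lie on the left with scores on component 1 of -10.0 or less, and the diets overlap on every day.

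The comparison of 1 d with -8 d asks how the liver changed over calving, averaged over the diets. The largest rises were in HP (haptoglobin, an acute phase protein; log2 fold change 4.84, SE 0.67) and GPX3 (a secreted glutathione peroxidase; 4.64, SE 0.25), with adjusted p of 3.4e-06 and 1.05e-13. HP was 10.63 ± 2.64 (SD, n = 5) in CON and 9.61 ± 2.50 (n = 5) in HIGH at -8 d, and 14.87 ± 0.02 (n = 4) and 14.87 ± 0.06 (n = 6) at 1 d, close to the highest value of the table, so the size and rank of its rise are uncertain. Next came LOC613358 (3.83, SE 0.48), the metallothionein MT1A (3.38, SE 0.44), CYP11A1 (side-chain cleavage of cholesterol; 2.66, SE 0.38), SAA3 (serum amyloid A; 2.64, SE 0.31), C5H12orf75 (2.48), the calgranulin S100A12 (2.43), CGREF1 (2.17) and the interferon-induced ISG15 (1.98). The largest falls were in the desaturases FADS2 (-2.93, SE 0.28) and SCD (-2.68, SE 0.27) and in SERPINA6 (corticosteroid-binding globulin; -2.21, SE 0.27). CGN1 (conglutinin; -1.88), DDIT4 (-1.76), CYP2C87 (-1.67), GADD45B (-1.64), IGFALS (-1.60), HSD17B2 (-1.54) and CA3 (-1.53) followed.

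Among the genes fixed in advance, PC (pyruvate carboxylase) rose by 1.53 (SE 0.12, adjusted p = 5.31e-10), from 10.30 ± 0.56 (SD, n = 5) to 11.82 ± 0.11 (n = 4) in CON and from 9.97 ± 0.17 (n = 5) to 11.52 ± 0.41 (n = 6) in HIGH. PCK1 (cytosolic phosphoenolpyruvate carboxykinase) was near 14 in every group and differed by 0.02 (SE 0.05, adjusted p = 0.754). Such bright values lie towards the top of the table, where changes are compressed, so a change of PCK1 is not excluded. ANGPTL4 (1.91), ACADVL (0.48) and MTTP (0.47) rose, and GPAM (-0.31) fell. IGF1 fell by 0.63 (SE 0.09) and GHR fell by 0.93 (SE 0.18), the latter in 1 of its 11 probe sets. G6PC1 (-0.10), PDK4 (-0.26), SREBF1 (-0.21), FASN (-0.37), SOCS2 (0.10), IGFBP1 (-0.21), PPARA (0.20) and DGAT2 (-0.16) did not pass, although a second probe set of G6PC1 passed with the opposite sign.

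Of 24 acute phase proteins, 16 rose and 2 fell (17 and 2 adjusted over the list alone), among them ITIH4 (1.53), SAA4 (1.57) and A2M (1.21). The list passed with the preset correlation (adjusted p = 1.7e-07), and had adjusted p = 0.0843 with an estimated correlation. Of 12 plasma proteins lowered in the acute phase, 10 fell and 1 rose (10 and 1 adjusted over the list alone). TTR (-0.32) and APOA2 (-0.15) fell and APOA1 (0.80) rose. The adjusted p of this list was 2.77e-06, and adjusted p = 0.0178 with an estimated correlation. Of 17 endoplasmic reticulum stress genes, which include chaperones of that compartment, 16 rose (17 adjusted over the list alone), with PDIA3 at 0.68, CALR at 0.99, PDIA4 at 0.84 and SEL1L at 0.61 (adjusted p = 1.57e-10). The list had adjusted p = 0.184 with an estimated correlation. Of 21 interferon-stimulated genes, 13 rose (17 adjusted over the list alone), such as USP18 (0.99), PARP9 (0.92), EPSTI1 (0.82) and IFIT5 (0.54). Their adjusted p was 2.16e-06, and adjusted p = 0.353 with an estimated correlation. Of 42 oxidative phosphorylation genes, 23 rose (26 adjusted over the list alone), with UQCRB at 0.69, CYC1 at 0.44, ATP5MC1 at 0.43 and ATP5MC3 at 0.33 (adjusted p = 2.4e-09). This list had adjusted p = 0.353 with an estimated correlation.

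Of 18 xenobiotic metabolism genes, 12 fell (12 adjusted over the list alone), among them CYP2D14 (-0.83), CYP2E1 (-0.52) and SULT1A1 (-0.34). The adjusted p was 2.16e-06, and adjusted p = 0.0942 with an estimated correlation. Of 14 fatty acid synthesis genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with ACSS2 at -1.52 and THRSP at -1.45 beside FADS2 and SCD. Its adjusted p was 0.00857, and adjusted p = 0.353 with an estimated correlation. Of 8 neutrophil markers, 4 rose (4 adjusted over the list alone), namely S100A12, S100A8 (1.66), S100A9 (0.80) and LTF (1.54), of which the S100 genes are also on the acute phase list (adjusted p = 0.00956, and adjusted p = 0.184 with an estimated correlation). Of 14 T and NK cell markers, 5 fell (7 adjusted over the list alone), such as CD3G (-0.46), PRF1 (-0.39), GZMB (-0.35) and CD5 (-0.24). This list had adjusted p = 0.00936, and adjusted p = 0.477 with an estimated correlation.

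The 23 other lists did not pass with the preset correlation. Members rose and fell in fatty acid oxidation (5 and 7 of 21, 8 and 7 adjusted over the list alone), where SLC22A5 rose by 0.97 and HADH was at -0.60 and ACADS at -0.50. The counts were 6 and 5 of 16 PPAR-alpha targets (8 and 5 adjusted over the list alone), with PLIN2 at 1.05 and CREB3L3 at 0.76, and 6 and 4 of 18 gluconeogenesis genes (6 and 5), with LDHB at 0.68, MDH2 at 0.37 and GLUD1 at -0.31. In triglyceride synthesis and lipoprotein assembly 7 rose and 4 fell of 17 (7 and 5), with APOA4 at 1.72, SAR1B at 0.53 and APOC3 at -0.31. In oxidative stress defence 9 rose and 4 fell of 22 (10 and 4), with GPX4 at 0.68 and GCLM at 0.57. In cholesterol synthesis 2 rose and 6 fell of 17 (2 and 6), with LSS at -0.70, TM7SF2 at -0.64, ACAT2 at -0.43 and EBP at -0.38. In the urea cycle and amino acid breakdown 5 rose and 7 fell of 24 (5 and 7), with OTC at -1.28, HPD at -0.74, BHMT at 0.91 and ARG1 at 0.66. In the citric acid cycle 7 rose and 3 fell of 15 (7 and 3), with IDH3A at 0.99, IDH2 at 0.70 and SUCLG1 at 0.36.

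The other lists that did not pass were the ATF4 and amino acid response (6 rose and 2 fell of 16, 7 and 2 adjusted over the list alone, with ATF4 at 0.70, TRIB3 at 0.59, ATF5 at 0.44 and CEBPB at 0.44), the growth hormone and IGF axis (2 and 4 of 12, 2 and 4, with IGFBP2 at 0.89 and IGFBP4 at 0.33), insulin signalling (3 and 2 of 15, 3 and 3, with PKLR at -0.90), and ketogenesis (1 fell of 2, 1 alone, ACAT1 at -0.13). In bile acid and sterol disposal 2 fell of 5 (2 alone), with ABCG8 at -1.37 and SLC27A5 at -0.24. Of 19 immediate early and heat shock genes 3 rose and 4 fell (3 and 4 alone), with ZFP36 at -0.99, DUSP1 at -1.08, KLF4 at 0.69 and IER2 at 0.51. Of 24 cell cycle genes 1 rose (0 alone), TYMS at 0.56, and of 17 antigen presentation genes 2 fell (0 alone), with BOLA-DRA at -0.23. Rises and falls numbered 5 and 7 of 15 hepatocyte markers (FGB 0.88), 1 and 1 of 14 Kupffer cell and macrophage markers (VSIG4 0.39, CD14 -0.38), 1 and 2 of 14 stellate cell and fibroblast markers (BGN -0.37), 3 and 2 of 15 endothelial markers (EMCN -0.66), 0 and 2 of 8 cholangiocyte markers (ANXA4 -0.15, TFF3 -0.44), 0 and 0 of 6 B and plasma cell markers and 0 and 0 of 7 erythroid markers. Adjusted over the list alone, these 7 counts were the same. Mean, median and test differed in sign for fatty acid oxidation, PPAR-alpha targets, triglyceride synthesis, insulin signalling, cell cycle, and hepatocyte, B cell and endothelial markers.

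In all, 5531 probe sets passed by limma, of which 2757 rose and 2774 fell. Those with at least a 1.5-fold change numbered 415 up and 261 down. By exact sign flips of the 8 cows with both days, 14 of the 32 lists passed, each in the same direction in 8 of 8 cows (adjusted p = 0.0179, p = 0.00781 being the smallest that 8 cows allow). These included the 9 lists that passed above. The 3' minus 5' difference of the elongation factor control probe sets was -0.684 ± 0.119 (SD, n = 10) at -8 d, -1.07 ± 0.154 (n = 10) at 1 d and -0.81 ± 0.134 (n = 12) at 9 d. This difference moved with the same days as these lists. The differences of GAPDH (0.543, 0.534 and 0.579 on these days), actin (1.60, 1.61 and 1.78) and cyclophilin (1.23, 1.19 and 1.25) changed little from -8 d to 1 d. Whether RNA quality bore on the lists was not tested.

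**Figure D2:**
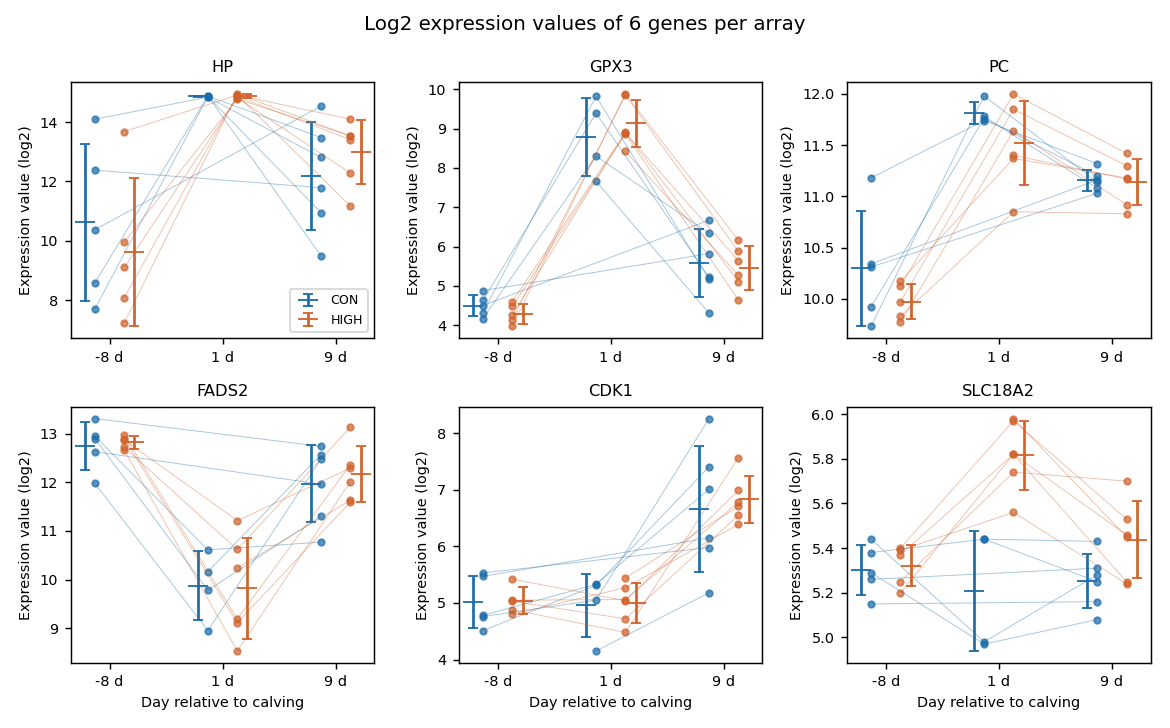
Log2 expression values of HP, GPX3, PC, FADS2, CDK1 and SLC18A2 per array, by day relative to calving (evenly spaced categories) and diet. Points are arrays, thin lines join the arrays of a cow, and bars show the group mean with the SD (n = 4 to 6). FADS2 was lower at 1 d than at -8 d in 8 of 8 cows, and CDK1 was higher at 9 d than at -8 d in 10 of 10 cows.

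At 9 d, the genes that had risen most from -8 d included RRM2, BIRC5, UBE2C, CDK1 and NUSAP1, which are on the cell cycle list. Besides HP (2.50, SE 0.63) and C5H12orf75 (2.08, SE 0.20) the genes were PCLAF (a PCNA-binding factor; 2.50, SE 0.33), CKAP2 (2.32), RRM2 (ribonucleotide reductase; 2.12, SE 0.27), STMN1 (1.89), BIRC5 (survivin; 1.88), UBE2C (1.85), CDK1 (1.75, SE 0.23) and NUSAP1 (1.71). HP was higher at 9 d than at -8 d in 8 of 10 cows and lower in 2. Its -8 d values ran from 7.70 to 14.10 in CON and from 7.23 to 13.68 in HIGH. CDK1 went from 5.01 ± 0.46 (SD, n = 5) to 6.67 ± 1.11 (n = 6) in CON and from 5.04 ± 0.24 (n = 5) to 6.83 ± 0.42 (n = 6) in HIGH. The largest falls were in CGN1 (conglutinin), the haemoglobin gene HBB (-1.59, 1 of 4 probe sets), the sterol transporter ABCG8 (-1.40), GADD45B (-1.36), BHLHE40 (-1.31), INHBA (-1.22), AK4 (-1.08), RGS16 (-1.03), SCARA5 and DIO1 (-0.99). AK4 (adjusted p = 0.0447) went from 8.84 ± 0.93 (SD, n = 5) to 6.89 ± 1.27 (n = 6) in CON and from 7.56 ± 0.88 (n = 5) to 7.24 ± 0.79 (n = 6) in HIGH, and its call was lost in many alternatives and that of INHBA with only the cows with all 3 days. Of the genes fixed in advance, PC (1.01, SE 0.12), FASN (0.85, SE 0.17), ANGPTL4 (0.79), ACADVL (0.35) and MTTP (0.29) were above -8 d, and SCD (-0.89), GHR (-0.67) and IGF1 (-0.36) below it. PCK1 (-0.02), G6PC1 (0.15), PDK4 (0.08), SREBF1 (-0.09), SOCS2 (0.20), IGFBP1 (-0.13), SAA3 (0.40), PPARA (-0.04), DGAT2 (-0.10) and GPAM (-0.10) did not pass.

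Of the 24 cell cycle genes, 23 rose (24 adjusted over the list alone) by a median of 0.99 (adjusted p = 5.62e-24, and adjusted p = 0.192 with an estimated correlation). Of 17 cholesterol synthesis genes, 10 rose (13 adjusted over the list alone), with HMGCS1 at 1.25, SQLE at 1.09, FDFT1 at 1.05 and CYP51A1 at 0.93. Their adjusted p was 5.6e-12, and adjusted p = 0.193 with an estimated correlation. In fatty acid oxidation 6 of 21 rose (9 adjusted over the list alone), among them SLC22A5 (0.68), ABCD3 (0.38) and ETFA (0.16), with adjusted p = 0.000319, and adjusted p = 0.234 with an estimated correlation. Of 16 PPAR-alpha targets 5 rose (7 rose and 1 fell adjusted over the list alone), such as VNN1 (0.92) and PLIN2 (0.63), with adjusted p = 0.00191, and adjusted p = 0.39 with an estimated correlation. Several PPAR-alpha targets are also on the fatty acid oxidation list. Of 18 gluconeogenesis genes 5 rose and 1 fell (6 and 1), with PPARGC1A at 0.75, LDHB at 0.61 and LDHA at 0.92, which also had a probe set past the threshold with the opposite sign (adjusted p = 0.00099, and adjusted p = 0.234 with an estimated correlation). In the urea cycle and amino acid breakdown 9 of 24 rose and 1 fell (10 and 1), with BHMT at 0.76, ARG1 at 0.70, AMT at 0.67 and CBS at 0.42 (adjusted p = 0.000395, and adjusted p = 0.234 with an estimated correlation).

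In the citric acid cycle 6 of 15 rose and 1 fell (6 and 1 adjusted over the list alone), with IDH2 at 0.70, OGDH at 0.60, IDH3A at 0.57 and CS at 0.44 (adjusted p = 0.000455, and adjusted p = 0.193 with an estimated correlation). In oxidative phosphorylation 7 of 42 rose (16 adjusted over the list alone), with CYC1 and UQCRB at 0.32 (adjusted p = 0.000327, and adjusted p = 0.471 with an estimated correlation). In oxidative stress defence 8 of 22 rose and 2 fell (9 and 3), with GPX3 at 1.16, SRXN1 at 0.73, GPX4 at 0.61 and FTH1 at -0.14 (adjusted p = 0.0242, and adjusted p = 0.234 with an estimated correlation). Of the plasma proteins lowered in the acute phase 4 of 12 fell and 1 rose (6 and 1), with SERPINA7 at -0.48, TTR at -0.20 and APOA1 at 0.97 (adjusted p = 0.0402, and adjusted p = 0.234 with an estimated correlation). Of 7 erythroid markers 2 fell (4 adjusted over the list alone), HBB and HBA (-0.23), with adjusted p = 0.0331, and adjusted p = 0.234 with an estimated correlation. Of 17 antigen presentation genes 1 fell (1 adjusted over the list alone), PSMB10 at -0.40, with adjusted p = 0.0199, and adjusted p = 0.471 with an estimated correlation. The neutrophil list (1 of 8 rose, LTF), the Kupffer cell list (0 of 14 past) and the T and NK cell list (CD2 at -0.20) did not pass. Mean, median and test differed in sign for fatty acid synthesis, bile acid disposal, ATF4, insulin signalling, and cholangiocyte markers.

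In all, 2266 probe sets passed by limma at 9 d against -8 d, 1245 up and 1021 down, and 20 of the 32 lists did not pass, the lowest of them at adjusted p = 0.0757. By exact sign flips of the 10 cows with both days, 13 lists passed. The cell cycle list mean was higher at 9 d in 10 of 10 cows by 1.11 on average (exact adjusted p = 0.00781), and the cholesterol synthesis mean was higher in 10 of 10 cows by 0.50 (exact adjusted p = 0.00781). Of the 2757 probe sets that rose by 1 d, 763 were also past the threshold upward at 9 d and 7 downward. Of the 2774 that fell, 620 were past it downward at 9 d and 20 upward. Both changes are taken from the same -8 d arrays, so part of this agreement is built in.

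From 1 d to 9 d, HP, SAA3, SAA4, GPX3 and the desaturases FADS2 and SCD changed in the direction opposite to that over calving. The same 1 d arrays enter both changes, so part of this opposition is built in for genes picked as extreme. Among the genes with the largest falls were GPX3 (-3.47, SE 0.24), LOC613358 (-2.38), HP (-2.33, SE 0.64), SAA3 (-2.23), MT1A (-2.05), SAA4 (-1.88), ISG15 (-1.86), NUCB2 (-1.69), LBP (the lipopolysaccharide-binding protein; -1.58) and HOPX (-1.52). The size of the fall of HP is uncertain, since its values at 1 d lay close to the highest of the table, and its call was lost with only the cows with all 3 days. FADS2 (2.21, SE 0.26) and SCD (1.78, SE 0.26) rose, together with PCLAF (2.62), CKAP2 (2.22), UBE2C (2.10), VNN1 (2.06), STMN1 (1.98), RRM2 (1.88), BIRC5 (1.78) and CDK1 (1.77). Of the genes fixed in advance, FASN (1.22) and IGF1 (0.26) rose, and PC (-0.52) and ANGPTL4 (-1.12) fell. PCK1 (-0.04), G6PC1 (0.25), PDK4 (0.33), SREBF1 (0.12), GHR (0.26), SOCS2 (0.10), IGFBP1 (0.09), ACADVL (-0.13), PPARA (-0.24), MTTP (-0.18), DGAT2 (0.06) and GPAM (0.21) did not pass.

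The calls of 5 lists held with an estimated correlation between 1 d and 9 d. Of 17 cholesterol synthesis genes 15 rose (15 adjusted over the list alone), such as TM7SF2 (0.94), LSS (0.82), NSDHL (0.66) and ACAT2 (0.59), with adjusted p = 0.0325 with an estimated correlation. Of 14 fatty acid synthesis genes 7 rose (7 adjusted over the list alone), including ACSS2 (1.39), with adjusted p = 0.0378 with an estimated correlation. Of 24 acute phase proteins 14 fell and 1 rose (15 and 1), including ITIH4 (-1.46), FGB (-1.19) and CP (-0.31), with adjusted p = 0.0242 with an estimated correlation. Of 12 plasma proteins lowered in the acute phase 6 rose (8 adjusted over the list alone), such as SERPINA6 (1.27), RBP4 (0.22) and ALB (0.08), with adjusted p = 0.0242 with an estimated correlation. Of 18 xenobiotic metabolism genes 10 rose and 1 fell (12 and 1), such as CYP1A1 (1.07), EPHX1 (0.65), CYP2D14 (0.65) and SULT1A1 (0.34), with adjusted p = 0.0376 with an estimated correlation.

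Further lists passed with the preset correlation only. Of the endoplasmic reticulum stress genes 16 of 17 fell (17 adjusted over the list alone), with CALR at -1.06, PDIA4 at -0.94, PDIA3 at -0.73 and DNAJC3 at -0.53 (adjusted p = 3.67e-14, and adjusted p = 0.0633 with an estimated correlation). Of the interferon-stimulated genes 16 of 21 fell (19 adjusted over the list alone), with PARP9 at -0.87, USP18 at -0.81 and IRF7 at -0.60 (adjusted p = 2.45e-11, and adjusted p = 0.0796 with an estimated correlation). Of the cell cycle genes 19 of 24 rose (20 adjusted over the list alone), including BUB1B at 1.48 (adjusted p = 1.59e-19, and adjusted p = 0.0633 with an estimated correlation). In the urea cycle and amino acid breakdown 9 of 24 rose (11 adjusted over the list alone), with OTC at 0.91, HPD at 0.62 and BCKDHA at 0.39 (adjusted p = 1.07e-06, and adjusted p = 0.0745 with an estimated correlation). In fatty acid oxidation 10 of 21 rose (11 rose and 1 fell adjusted over the list alone), with HADH at 0.66, ACADS at 0.54 and ACAA2 at 0.46 (adjusted p = 8.32e-05, and adjusted p = 0.178 with an estimated correlation). In oxidative phosphorylation 11 of 42 fell (13 adjusted over the list alone), with UQCRB at -0.37 and NDUFB9 at -0.21 (adjusted p = 1.01e-05, and adjusted p = 0.405 with an estimated correlation). Of 5 bile acid and sterol disposal genes 2 rose (3 adjusted over the list alone), CYP27A1 (0.23) and SLC10A1 (0.21), with adjusted p = 0.0248, and adjusted p = 0.178 with an estimated correlation. Of 8 neutrophil markers 3 fell (3 adjusted over the list alone), with S100A8 at -1.37, S100A12 at -1.35 and S100A9 at -0.59 (adjusted p = 0.0148, and adjusted p = 0.119 with an estimated correlation).

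In all, 3146 probe sets passed between 1 d and 9 d, 1467 up and 1679 down, and 19 of the 32 lists did not pass, the lowest at adjusted p = 0.0635. Mean and median differed in sign for hepatocyte markers. By exact sign flips of 10 cows, 17 lists passed. Acute phase and endoplasmic reticulum list means were lower at 9 d in 10 of 10 cows (exact adjusted p = 0.00694 for each).

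**Figure D3:**
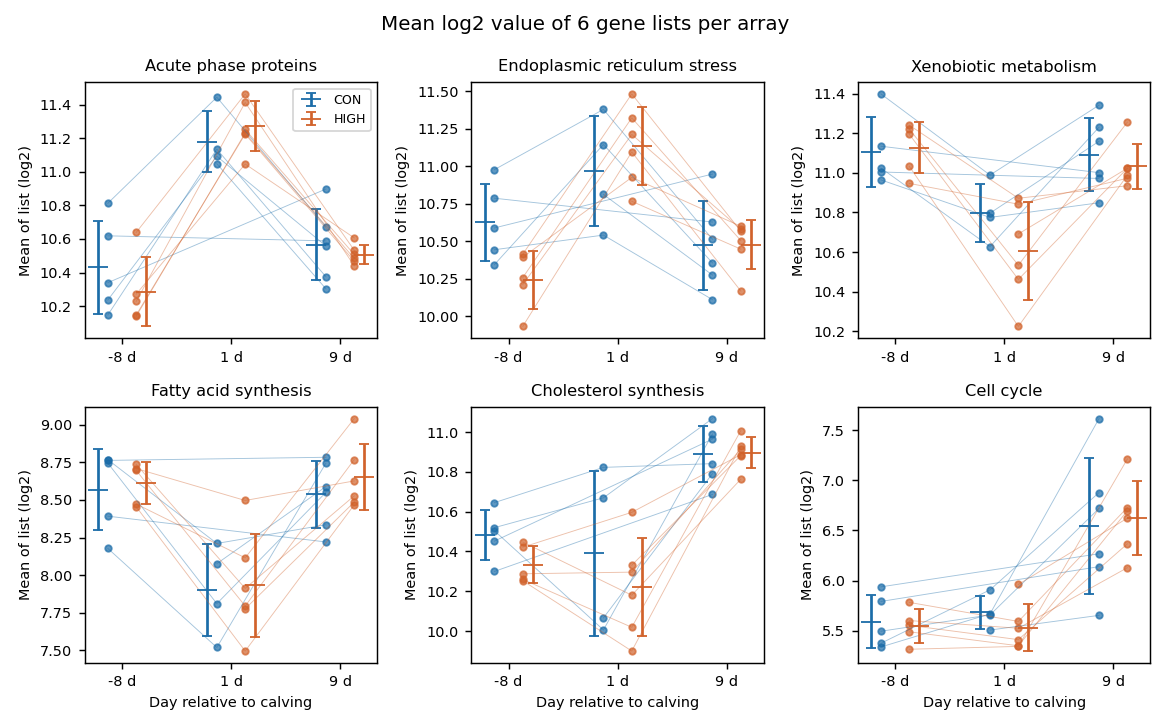
Mean log2 value of 6 gene lists per array, by day relative to calving (evenly spaced categories) and diet. Points are arrays, thin lines join the arrays of a cow, and bars show the group mean with the SD (n = 4 to 6). The cell cycle mean was higher at 9 d than at -8 d in 10 of 10 cows, and the endoplasmic reticulum mean at -8 d was 10.63 ± 0.26 in CON and 10.24 ± 0.19 in HIGH (SD, n = 5 each).

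Within the diets, the same comparisons gave fewer calls in CON. CON had fewer arrays than HIGH at 1 d and as many at -8 d and 9 d. At 1 d against -8 d, 1523 probe sets passed in CON (799 up, 724 down) and 3982 in HIGH (2090 up, 1892 down). At 9 d against -8 d these were 441 in CON (252 up, 189 down) and 855 in HIGH (583 up, 272 down). At 1 d, 1030 passed in both diets, all 1030 in the same direction, where 127 would do so if the diets were independent. At 9 d this held for 280 of 280, with 8.26 given by independence. Across probe sets, the changes in CON and HIGH correlated with r of 0.733 at 1 d and 0.721 at 9 d, and these changes share no arrays. Leaving out cow 483 lowered the CON counts to 446 and 62, and leaving out cow 462 lowered the HIGH count at 9 d to 322.

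The diets were compared on each day to ask how energy intake before calving bears on the liver. At -8 d the smallest p belonged to SMIM10 (0.80, SE 0.16), GHDC (0.33), the macrophage metal transporter SLC11A1 (1.15, SE 0.26), DNAAF11 (0.40), OPTC (0.30), MORC4 (-0.44), GSTT1 (0.85), CD209 (0.68), SOD3 (1.01) and HEY1 (0.31), given as HIGH minus CON, and none passed. Among the genes fixed in advance, SAA3 (-0.94, SE 0.46), HP (-0.94, SE 0.99) and PC (-0.32, SE 0.18) did not pass, nor did any other. With limma, 0 probe sets passed (smallest adjusted p = 0.586), and 1025 had an unadjusted p under 0.05 (4.27%, less than the share of 0.05 given by chance). Of the lists, 7 passed with the preset correlation and 0 of them with an estimated correlation. The endoplasmic reticulum stress list was lower in HIGH by a mean of -0.39, with HSPA5 (the chaperone BiP) at -0.60, HSP90B1 at -0.38, SEL1L at -0.34 and PDIA3 at -0.33, none past the threshold (list adjusted p = 9.98e-13, and adjusted p = 0.55 with an estimated correlation). Kupffer cell and macrophage markers were higher in HIGH (mean 0.24, with CD68 at 0.42 and FCER1G at 0.41, adjusted p = 9.22e-06, and adjusted p = 0.755 with an estimated correlation). The list mean of cow 483 in CON was 9.31, against 9.61 to 9.68 in the other CON arrays and 9.65 to 10.07 in HIGH. This difference therefore rests in part on that array.

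At -8 d the interferon-stimulated genes (mean 0.21, adjusted p = 0.00251), T and NK cell markers (0.14, adjusted p = 0.00841) and antigen presentation genes (0.09, adjusted p = 0.0056) were also higher in HIGH with the preset correlation. Oxidative phosphorylation (-0.06, adjusted p = 0.00127) and cholesterol synthesis (-0.14, adjusted p = 0.0201) were lower. Each of these 5 lists had adjusted p = 0.804 with an estimated correlation. The T and NK cell mean of cow 445 in CON was 5.81, and the next lowest array had 6.004. In HIGH, cow 460 had an antigen presentation mean of 8.28 (next highest 8.14) and an interferon mean of 7.47 (next highest 7.25). The differences of the T and NK cell, antigen presentation and interferon lists therefore rest in part on a single array each. By exact permutation of the cows, the smallest adjusted p of a list mean was 0.381, but if 1 list alone had the smallest p that these cows allow its adjusted p would be 0.254, so this says little.

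At 1 d, SLC18A2 (a vesicular monoamine transporter) was the 1 gene past the threshold. It was 5.21 ± 0.27 (SD, n = 4) in CON and 5.82 ± 0.16 (n = 6) in HIGH, a difference of 0.61 (SE 0.10, adjusted p = 0.0321 by limma), with 6 of 6 HIGH arrays (5.56 to 5.98) above 4 of 4 CON arrays (4.97 to 5.44). Both group means lie below the array medians. The next genes were UBN2 (0.37), the apolipoproteins APOA5 (-0.78, SE 0.16) and APON (-0.78, SE 0.16), MCEE (-0.48), BNIP3 (-0.37), ANKRD13A (-0.51), NT5C2 (-0.51), SLC17A9 (1.11) and AP3S1 (0.61), with adjusted p of 0.126 or more. None of the genes fixed in advance passed, with PDK4 at -0.59 (SE 0.34), ANGPTL4 at -0.50 (SE 0.29) and ACADVL at -0.25 (SE 0.11). The SLC18A2 call was lost when only the 1 d arrays were fitted (adjusted p = 0.952) and when the -8 d array of cow 445 and the 9 d array of cow 528 were left out, an alternative added after seeing the data (adjusted p = 0.0522). It was also lost with only the cows with all 3 days (adjusted p = 0.0801), with array quality weights (adjusted p = 0.131), without cow 439, 445, 462, 483, 512, 527, 528 or 529, and without CON 1 d replicate 1 or 3 or HIGH 1 d replicate 3, 5 or 6. An unadjusted p under 0.05 was found for 2013 probe sets (8.38%, more than the share of 0.05 given by chance). Probe sets vary together, so this is not a count of independent results.

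With the preset correlation 5 lists passed at 1 d. Fatty acid oxidation was lower in HIGH (mean -0.20, adjusted p = 2.65e-08, and adjusted p = 0.33 with an estimated correlation), with 0 of 21 members past over all probe sets and 6 adjusted over the list alone, and with ACADL at -0.43, DECR1 at -0.36, ACADS at -0.28 and ACADM at -0.21. PPAR-alpha targets were lower (mean -0.32, adjusted p = 4.97e-08, and adjusted p = 0.33 with an estimated correlation), with CREB3L3 at -0.49 and CYP4A11 at -0.41. The fatty acid oxidation means in CON were 11.31 and 11.35 in cows 477 and 483, and 10.93 and 11.08 in cows 445 and 510. In HIGH they ran from 10.74 to 11.06. The PPAR-alpha target means of these CON cows were, in that order, 11.30, 11.31, 10.49 and 10.88, against 10.25 to 10.85 in HIGH. Both differences therefore rest largely on cows 477 and 483. Cholesterol synthesis was lower (-0.16, adjusted p = 0.00703, and adjusted p = 0.675 with an estimated correlation). Its list means in CON were 10.82 and 10.67 in cows 477 and 483, and 10.01 and 10.07 in cows 445 and 510. In HIGH they ran from 9.90 to 10.60, so the difference rests on cows 477 and 483. Interferon-stimulated genes (0.27, adjusted p = 0.000185, and adjusted p = 0.588 with an estimated correlation) and endoplasmic reticulum stress genes (0.14, adjusted p = 0.0212, and adjusted p = 0.675 with an estimated correlation) were higher. The endoplasmic reticulum means in CON were 11.38, 10.54 (cow 477), 11.15 and 10.81, against 10.77 to 11.48 in HIGH, so the difference rests largely on cow 477. The interferon mean of cow 445 in CON, 8.19, lay above the highest in HIGH, 8.15. By exact permutation of cows, triglyceride synthesis and lipoprotein assembly (-0.18) had the smallest p that 4 against 6 cows allow (exact p = 0.00476). After adjustment this is 0.152, the lowest for 1 list alone, so no list could pass by itself.

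At 9 d the smallest p belonged to TEDC2 (0.34), EXOSC6 (0.30), MANEAL (-0.36), PRMT2 (0.36), PTPMT1 (0.30), CTPS2 (-0.29), SLC17A9 (0.83, SE 0.23), FCN1 (-0.57), GSTT1 (0.70, SE 0.20) and IRF2 (0.33). SAA3 differed by -0.94 (SE 0.42), HP by 0.83 (SE 0.91) and FASN by 0.19 (SE 0.25). With limma, 0 probe sets passed (smallest adjusted p = 0.998), and 813 had an unadjusted p under 0.05 (3.39%, less than the share of 0.05 given by chance). With the preset correlation 0 of 32 lists passed by the limma camera test (smallest adjusted p = 0.431), and by exact permutation of cows the smallest adjusted p was 0.972, where 1 list alone can reach 0.0693.

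Whether the change over calving differed between the diets was tested directly. At 1 d the smallest p belonged to the disulfide isomerase PDIA3 (0.65, SE 0.14), ATOH1 (-0.38), APON (-0.97, SE 0.22), SLC18A2 (0.60, SE 0.14) and FKBP2 (0.58), given as the change in HIGH minus that in CON, each with adjusted p = 0.353. PDIA3 went from 12.61 ± 0.10 (SD, n = 5) to 12.96 ± 0.27 (n = 4) in CON and from 12.30 ± 0.13 (n = 5) to 13.30 ± 0.22 (n = 6) in HIGH. At 9 d they were HEY1 (-0.43), PDYN (0.46), CLDN10 (-0.38), CERS4 (-0.32) and COL10A1 (0.46), each with adjusted p = 1.00. With limma, 0 probe sets passed at 1 d and 0 at 9 d, and 1723 and 789 had an unadjusted p under 0.05. These are 7.17% and 3.29%, above and below the share of 0.05 given by chance.

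Of the lists, 5 passed for diet by time at 1 d and 5 at 9 d with the preset correlation, and 0 with an estimated correlation. The arrays of the diet comparison before calving enter these changes too, so these list results are not independent of that comparison. The endoplasmic reticulum stress list rose more in HIGH by a mean of 0.53 at 1 d (adjusted p = 1.42e-11, and adjusted p = 0.329 with an estimated correlation), with 0 of 17 members past over all probe sets and 4 adjusted over the list alone. By exact permutation of the cows with both days, the smallest adjusted p of a list mean was 0.5 at 1 d and 0.825 at 9 d, but 1 list alone at the smallest p that the cows allow would have 0.571 and 0.254, so these tests say little.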

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

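Tests chosen only after the result was seen were those of exchanged labels and RNA quality for cow 445, of leukocytes and of single cows for the cell cycle genes, and all 3 of the endoplasmic reticulum list at -8 d, as well as the exact tests of list means.

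Single arrays lay far from the others of their group in 26 of 372 sets of values, where chance gives about 18.6 (5 of 36 array measures, 12 of 192 list means and 9 of 144 genes, against 1.8, 9.6 and 7.2). In CON at -8 d, cow 445 had a 3' minus 5' difference of cyclophilin of 1.31 (others 1.17 to 1.21) and ANGPTL4 at 8.01 (6.96 to 7.17), and cow 483 a Kupffer cell list mean of 9.31 (9.61 to 9.68). In HIGH at -8 d, cow 529 had an acute phase mean of 10.64 (10.14 to 10.27), cow 432 FASN at 7.60 (7.86 to 7.96) and cow 439 APOA5 at 12.41 (12.11 to 12.19). In CON at 1 d, cow 477 scored -10.0 on the first principal component (-22.3 to -21.0) with PC, pyruvate carboxylase, at 11.98 (11.74 to 11.78). Cow 445 had a gluconeogenesis mean of 11.055 (11.33 to 11.37) and cow 483 an immediate early mean of 8.58 (8.79 to 8.83). In HIGH at 1 d, cow 462 had a cyclophilin difference of 1.20 (1.24 to 1.25), cow 529 a PPAR-alpha target mean of 10.25 (10.66 to 10.85) and cow 432 IGF1 at 8.61 (7.65 to 7.87). Cow 439 had a mean of the lowered plasma proteins of 12.47 (12.59 to 12.64) and SAA3 at 13.34 (10.50 to 11.13).

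In CON at 9 d, cow 528 had a 3' minus 5' difference of actin of 3.87 (others 1.48 to 1.75) and cow 445 a T and NK cell mean of 5.73 (6.07 to 6.26). Cow 483 had an interferon-stimulated mean of 7.76 (6.76 to 7.11) and an antigen presentation mean of 8.34 (7.77 to 7.98), and cow 477 a neutrophil mean of 6.27 (5.55 to 5.73) and SAA3 at 11.61 (9.03 to 9.80). In HIGH at 9 d, cow 432 had an actin difference of 2.19 (1.32 to 1.59), an endoplasmic reticulum mean of 10.17 (10.45 to 10.60), GHR at 10.87 (9.53 to 9.88) and HSPA5 at 12.16 (12.49 to 12.63), and cow 529 a xenobiotic mean of 11.26 (10.935 to 11.02).

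The change from -8 d differed between the diets for 10 list results with the preset correlation and for 0 with an estimated one. At 1 d, HIGH minus CON, the mean differences were 0.53 for endoplasmic reticulum stress, -0.20 for fatty acid oxidation, -0.36 for PPAR-alpha targets, -0.13 for the urea cycle and 0.0519 for oxidative phosphorylation. At 9 d they were 0.39 for endoplasmic reticulum stress, -0.28 for Kupffer cell markers, -0.19 for interferon-stimulated genes, -0.10 for antigen presentation and 0.0609 for oxidative phosphorylation. The same -8 d arrays enter these changes and the diet comparison at -8 d. There the list means of the 9 d lists differed with the opposite sign, in that order by -0.387, 0.237, 0.184, 0.0718 and -0.0528. At 9 d itself they differed by 0.00618, -0.0406, 0.0218, -0.00902 and 0.00571, so these 9 d results largely restate the -8 d difference. At 1 d the endoplasmic reticulum means differed by 0.165, and those of fatty acid oxidation by -0.204, against -0.004 at -8 d. The fatty acid oxidation difference at 1 d rests largely on CON cows 477 and 483 (11.31 and 11.35, against 10.93 and 11.08 in cows 445 and 510).

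The -8 d array of cow 445 scored 0.464 on an axis from the -8 d mean (0) to the 1 d mean (1), and the other -8 d arrays -0.086 to 0.182. An exchange with the 1 d array of the same cow is argued against by the score of that array, 0.865. Of its 4 3' minus 5' differences 1 lay outside the range of the other -8 d arrays, so poorer RNA remains open. A biopsy closer to calving could also give this score, and was not tested because the calving dates are not in the labels.

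Cell cycle genes rose at 9 d by a mean of 1.02 (SE 0.12 over 24 genes). A few cows as the source is argued against, since the list mean was higher in 10 of 10 cows. By their mean over all arrays, 6 of the 23 genes that rose were among the dimmest probe sets. That mean includes the 9 d arrays, where these genes were higher, so it does not show their level at -8 d. At -8 d the list mean was 5.57, below the lowest array median of 5.87, so values near the background at -8 d remain open. The highest mean change of the 4 leukocyte marker lists was 0.324 (neutrophils, SE 0.17 over 8 markers, a wide spread). These standard errors treat genes as replicates and do not measure the spread over cows. A larger share of leukocytes therefore cannot be told apart from division of liver cells by this test. The other 3 lists changed by -0.04 (Kupffer cells), -0.10 (T and NK cells) and 0.07 (B cells).

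Endoplasmic reticulum stress genes were lower in HIGH at -8 d in the list mean (-0.387, exact p = 0.0317), and this list had adjusted p = 0.55 with an estimated correlation. Without cow 445 the difference was -0.299 (exact p = 0.0556), which argues against this array as the whole source. Chance among the cows remains open, since the exact p adjusted over the 32 lists was 0.381 and 1 list alone at the smallest p that these cows allow would have 0.254, so that this test decides nothing. In the same comparison the list means of Kupffer cell (0.237, exact p = 0.0238) and neutrophil markers (0.256, exact p = 0.0397) were higher in HIGH and that of hepatocyte markers was lower (-0.0716, exact p = 0.0794), each with an adjusted p of 0.381 or more, so a different mix of cells, which was not tested as a cause, stays open. The smallest exact p of the 4 3' minus 5' differences between the diets was 0.333, which does not exclude a difference in RNA quality, and an effect of the diet likewise remains open.

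Labels were exchanged between cows for diet. For time, days were exchanged within cows that had both days, and among the unpaired arrays of a diet. For the time results averaged over the diets chance is argued against, since 1 split of 100, the real one, gave as many probe sets in each. For 1 d against -8 d the real count was 5531 and the highest other of 100 splits 2655, for 9 d against -8 d 2266 and 58 of 100, and for 9 d against 1 d 3146 and 1083 of 100. In CON these were 1523 and 538 of 24 splits at 1 d and 441 and 221 of 32 at 9 d, and in HIGH 3982 and 2863 of 32 at 1 d and 855 and 95 of 32 at 9 d. Within a diet the real split also gave the largest count, but only 24 or 32 splits were possible. The largest of so few, without adjustment over the contrasts, does not exclude chance there. Some of the highest others exchange nearly all labels (18 of 22 arrays for 9 d against 1 d, 10 of 11 for CON 9 d, HIGH 1 d and HIGH 9 d), which makes them near mirrors of the real split. Chance cannot be excluded for diet at 1 d, where 41 of 100 splits gave as many (real 1, highest other 913). Where the real count is 0, every split gives as many and the splits decide nothing, which holds for diet at -8 d (100 of 100, real 0, highest other 1), diet at 9 d (100 of 100, real 0, highest other 1), diet by time at 1 d (100 of 100, real 0, highest other 29) and diet by time at 9 d (100 of 100, real 0, highest other 16). The split with 913 set cows 445, 439, 462 and 529 against the other 1 d arrays, a structure among these arrays that does not follow diet.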

How the results depend on the processing

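Leaving out 2 arrays together (cow 445 at -8 d, cow 528 at 9 d) was chosen after the data were seen. Values are given where a count changed by more than 1.5 times or to or from 0. The 2 arrays moved the diet count at 1 d from 1 to 0. That count was also 0 with only the groups of the contrast, only cows with 3 days, or array weights, and 2 without the cow block, with further quantile normalization or with median centring. Without the block, CON 9 d against -8 d went from 441 to 192 and HIGH 9 d against -8 d from 855 to 529. With only the groups of the contrast, CON 1 d against -8 d was 594 and HIGH 9 d 1324, and with array weights CON 9 d was 740 and HIGH 9 d 1479. Fewer arrays were used with only the cows with 3 days, giving 1137 (time 9 d against -8 d), 1886 (time 9 d against 1 d), 357 (CON 1 d), 188 (CON 9 d) and 568 (HIGH 9 d). There 3 list differences reversed, list endoplasmic reticulum stress, diet at 9 d, to 0.157, list cell cycle, diet at 9 d, to -0.444 and list cell cycle, diet by time 9 d, to -0.589. With 1 probe set per gene fewer were tested, and the counts were 2888 (time 1 d against -8 d), 1470 and 1896 for time, 951 for CON 1 d and 2263 for HIGH 1 d against -8 d. A minimum of 1.5-fold left 676, 341 and 425, and 482, 181, 791 and 278 for CON 1 d, CON 9 d, HIGH 1 d and HIGH 9 d. With an estimated correlation 6 of 56 list calls passed. Leaving out arrays or cows gave 4156 to 5595, 1596 to 2411 and 2390 to 3286 for the time contrasts, 446 to 1837 (CON 1 d), 62 to 500 (CON 9 d), 2668 to 4096 (HIGH 1 d), 322 to 935 (HIGH 9 d), 51 to 70 lists, 0 to 5 (diet 1 d), 0 to 1 (diet by time 1 d, where 1 came without the 1 d array of cow 445) and 0 for diet at -8 d, diet at 9 d and diet by time at 9 d by limma. CON 1 d was 446, 881 and 975 without cows 483, 477 and 510, and 939, 984, 783 and 1009 without CON -8 d replicates 2 and 3 and CON 1 d replicates 3 and 4. CON 9 d was 62, 86, 205 and 245 without cows 483, 477, 528 and 527, 133, 155, 214 and 282 without CON -8 d replicates 2 to 5, and 238, 238, 188 and 293 without CON 9 d replicates 1, 2, 3 and 6. HIGH 9 d was 322, 375, 408 and 557 without cows 462, 439, 460 and 529, 543, 480 and 509 without HIGH -8 d replicates 1, 3 and 4, and 523 and 508 without HIGH 9 d replicates 3 and 5. Diet at 1 d was 0 without cow 439, 462, 483, 512, 527, 528 or 529, CON 1 d replicate 3 or HIGH 1 d replicate 3, 5 or 6, 2 without cow 477 or 510, CON 1 d replicate 2 or CON 9 d replicate 4, 3 without cow 445 or CON 1 d replicate 1 or 4, and 5 without HIGH 1 d replicate 1. Cow as a fixed effect, the dimmest probe sets left out and the 2 other variance models changed none of the counts they gave by more than 1.5 times, although most of them shifted. Cow as a fixed effect gave no counts for diet at -8 d, 1 d or 9 d, since each cow had 1 diet. Of 60 largest changes, 0 reversed in 3420 tests by limma and 27 lost their call, in 3 genes (AK4, INHBA and HP). Where no cause is named, the cause was not tested. Probe sets near the background limit what small changes the arrays show.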

Other observations

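The gene families below were gathered by gene symbol after the data were seen, and their p was adjusted over 18 families. Of 108 tests over the contrasts of diet and time, 20 passed with the preset correlation and 0 with an estimated one, and the 20 are given here. From -8 d to 1 d, 11 of 25 cytochrome P450 genes fell and 1, CYP11A1, rose (adjusted p = 0.00109, and adjusted p = 0.36 with an estimated correlation), with CYP2C89 at -1.16 and CYP2U1 at -0.73. Of 55 secretory pathway genes with symbols in COP, SEC, TRAPPC or TMED 23 rose and 6 fell, with the signal peptidase subunit SEC11C at 0.87 and the translocon channel SEC61A1 at 0.77 (adjusted p = 0.00968, and adjusted p = 0.41 with an estimated correlation). Of 67 mitochondrial ribosomal proteins 21 rose and 4 fell (adjusted p = 0.0253, and adjusted p = 0.483 with an estimated correlation).

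From -8 d to 9 d, 4 of 6 MCM genes, which encode subunits of the replicative helicase, rose, with MCM6 at 0.88 and MCM4 at 0.60 (adjusted p = 0.00454, and adjusted p = 0.461 with an estimated correlation). Of 17 kinesins 6 rose, with KIFC1 at 0.72 and KIF23 at 0.64 (adjusted p = 0.00265, and adjusted p = 0.313 with an estimated correlation). Of 74 ribosomal proteins 5 fell and 1 rose (adjusted p = 0.019, and adjusted p = 0.856 with an estimated correlation).

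From 1 d to 9 d, 11 P450 genes rose and 1 fell (adjusted p = 9.07e-06, and adjusted p = 0.0816 with an estimated correlation), and 4 of 6 glutathione S-transferases rose (adjusted p = 0.00527, and adjusted p = 0.0976 with an estimated correlation). Of 15 aminoacyl tRNA synthetases 8 fell, with MARS1 at -0.56 and YARS1 at -0.45 (adjusted p = 0.00434, and adjusted p = 0.539 with an estimated correlation). Of the ribosomal proteins 15 fell and 1 rose (adjusted p = 0.00527, and adjusted p = 0.622 with an estimated correlation), and of 40 proteasome subunits 8 fell and 1 rose (adjusted p = 0.0161, and adjusted p = 0.559 with an estimated correlation). Kinesins (6 of 17 rose), S100 proteins (5 of 12 fell) and the secretory pathway genes (16 fell and 3 rose) each had adjusted p = 0.0221, and adjusted p = 0.539, 0.539 and 0.559 with an estimated correlation.

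Between the diets, no member of the families given next passed by itself. At -8 d the means in HIGH were lower for ribosomal proteins (-0.04, adjusted p = 0.0069), mitochondrial ribosomal proteins (-0.05, adjusted p = 0.0188), aminoacyl tRNA synthetases (-0.12, adjusted p = 0.0266) and secretory pathway genes (-0.06, adjusted p = 0.0188), each with adjusted p = 0.695 with an estimated correlation. Ribosomal proteins were higher in HIGH at 1 d (0.06, adjusted p = 1.34e-06, and adjusted p = 0.851 with an estimated correlation) and mitochondrial ribosomal proteins at 9 d (0.07, adjusted p = 3.63e-05, and adjusted p = 0.899 with an estimated correlation).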
